A study of Rattus norvegicus with 15 samples.

How the data were processed

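Gene expression was measured in primary rat hepatocytes on one-colour Agilent microarrays at 5 times in monolayer culture, 0, 6, 12, 24 and 48 h, with 3 arrays per time and 15 arrays in all. Per the labels' protocols, cells isolated from the liver were plated on collagen I, non-attached cells were washed away some hours later, and the medium was then replaced with serum-free William's E. RNA was extracted with a column kit and labelled with Cy3 as cRNA by the Quick Amp one-colour method, also per the labels' protocols. The series text describes independent experiments with different biological replicates at each time, and whether the same animal gave the cells of 1 replicate number at several times is not given in the sources used here.

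The values used were the authors' deposited table of 51323 probes, read as log2 signal. Per the submitters' processing notes, signals were extracted with Agilent Feature Extraction, version not given. The background correction and the normalization software are not given in the sources used here. In the deposited log2 values, the sorted values of 14 arrays were equal within 0.01, which is what quantile normalization of the arrays leaves. The array of 6 h replicate 3 differed in its lowest values, with 11390 probes (22.2%) tied at 1.38. Every array had a median of 4.03 and a 75th percentile of 6.65, so no further normalization was applied. Normalization to a common distribution removes any change in the total signal per array, and all fold changes are relative to that distribution. No array repeated another, the smallest median absolute difference between 2 arrays being 0.26.

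The table holds probe IDs without gene names, and no table pairing these probes with genes was used here. Before the data were examined, tests per gene, 36 gene lists of 809 genes (including markers of other liver cell types) and a rule for about 20 to 30 named genes had been planned. Without gene names the unit tested was the probe, and the lists, the marker genes and the alternatives that summarise several probes per gene were not analysed here. Rat GAPDH and PGK1, each with a pair of probes that carry the gene name in their ID, were the exception. Both names matched rat RefSeq symbols and both belong to the planned list of 19 glycolysis genes, so a Benjamini-Hochberg adjustment over these 4 probes is given as adjusted over the list alone. No coordinates are given, since no genome build is named for the array. Tested probes numbered 51259, of which 30418 have IDs starting with A, 20837 have IDs starting with CUST and 4 are the rat GAPDH and PGK1 probes. The other 64 probes, which are controls, were left out of the tests.

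Tests used limma 3.58.1 in R 4.3.3, with lmFit on 5 group means over all 15 arrays, eBayes, two-sided moderated tests and Benjamini-Hochberg adjustment over the 51259 probes. A probe was called at an adjusted p under 0.05 with no minimum fold. The comparisons were each later time against 0 h, each time against the one before it, any difference among the times (F test), and 48 h against 6 h, which was used to see whether early changes lasted. Overlaps of calls were set beside those of 50 simulated sets of unchanged groups with each probe's own spread, and of 50 more with each probe's replicate effects fitted with the block, using lists of the observed lengths taken by p in each direction; these lists were chosen after seeing the data. An exact permutation test was used for single quantities, and with 3 arrays against 3 its two-sided p cannot fall below 0.1. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.39. On simulated data for the comparison of 48 h with 0 h, with 200 of 51259 probes changed, 2%, 56.5% and 85.5% of the changed probes were recovered at true log2 changes of 1, 2 and 3. In the real comparison 9826 probes were called, which makes the adjustment less strict, so these shares do not carry over to it.

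Named probes followed the planned rule as far as probe IDs allow. They are the 2 probes with the largest rise and the 2 with the largest fall at 48 h against 0 h among called probes whose 3 arrays at 48 h all lay beyond those at 0 h and whose higher group mean exceeded the median of all values. Being picked for size, their values at 48 h can overstate the change. A probe was counted as above background on an array where its value exceeded that of the DarkCorner negative control.

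The replicate number was not a term of the planned fit, and a fit with it as a block was chosen beforehand for comparison. Deviations from the time means correlated above 0.1 in 28 of 30 same-numbered pairs of arrays (median r = 0.302, across probes), against a median of -0.172 for different numbers. Deviations cancel within each time, so the negative median follows from the positive one and adds no evidence of its own. All 3 numbers passed in 9 of the 10 pairs of times, so the numbers were taken to pair the arrays there. The exception was 0 h with 48 h, where numbers 1 and 2 gave 0.084 and 0.0765 and number 3 gave 0.368. Missing the limit does not show that same-numbered arrays were unrelated at these times. The pairing comes from these correlations and not from the labels. Other settings chosen beforehand were shifts to equal medians or 75th percentiles, quantile normalization of the tested probes, leaving out the dimmest probes (the bottom tercile by mean level), a minimum 2-fold change, limma treat against a 1.5-fold change, eBayes with trend and robust settings, only the 2 times compared, and each array left out in turn. Chosen after seeing the data were a shift of each array to equal means of 7 E1A control probes, that shift with the replicate block, and a floor at the lowest value of 6 h replicate 3.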

Results

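Primary rat hepatocytes, cells isolated from the liver, were profiled at 0, 6, 12, 24 and 48 h of monolayer culture, with 3 arrays from separate experiments at each time. The comparisons against 0 h were planned as against freshly isolated cells. Per the labels' protocols, plating, removal of non-attached cells and a change of medium followed isolation. Effects of these steps cannot be told apart from those of time in culture in the differences from 0 h. The series concerns dedifferentiation, the loss of hepatocyte characteristics in culture. Values are deposited log2 signals of 51259 tested probes, which carry IDs and, except for rat GAPDH and PGK1, no gene names here. The planned gene lists and markers of other liver cells were therefore not tested. Across probes, arrays of one time correlated at r = 0.923 to 0.934 at 0 h and at r = 0.965 to 0.970 at 12 h. The first principal component held 31.6% of the variance and separated the 0 h arrays (-185.7 to -142.2) from the 48 h arrays (63.8 to 132.1). Replicate 3 of every time lay lowest on the second component, which held 14.6%.

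**Figure D1:**
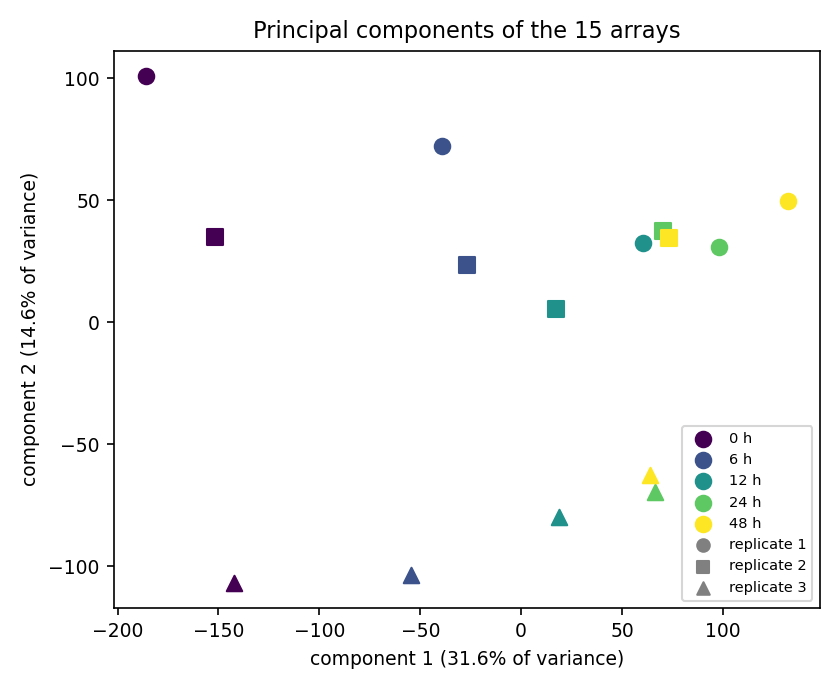
Scores of the 15 arrays on the first 2 principal components of the 51259 probes (axes in component units), with colour for hours in culture and shape for replicate number. The 0 h arrays lie at the left (-185.7 to -142.2), and replicate 3 of each time lies lowest on the second component.

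After 48 h, both probes of rat GAPDH, a glycolytic enzyme often used as a reference gene, gave higher signal than at 0 h. Rat-GAPDH_3 rose 3.24-fold, from 13.29 ± 0.44 to 14.98 ± 0.35 (log2 signal, mean ± SD, n = 3), a log2 change of 1.69 with SE 0.24 and adjusted p = 0.000417 by limma. Rat-GAPDH_5 rose 2.89-fold, a log2 change of 1.53 with SE 0.22 and adjusted p = 0.000537. Every 48 h array lay above every 0 h array for both probes, and the p adjusted over the list alone was 3.54e-05 for each. For rat PGK1, the enzyme that follows GAPDH in glycolysis, Rat-PGK1_3 gave a log2 difference of -0.09 (SE 0.19, adjusted p = 0.809) and Rat-PGK1_5 one of -0.33 (SE 0.18, adjusted p = 0.249), so neither probe passed the test over all probes or over the list alone. The E1A control probes, adenovirus sequences that do not measure rat RNA, averaged 8.09 ± 0.14 at 0 h and 7.49 ± 0.36 at 48 h (n = 3). With arrays shifted to equal E1A control probes the differences turned to 0.51 for Rat-PGK1_3 and 0.27 for Rat-PGK1_5, while those of Rat-GAPDH_3 and Rat-GAPDH_5 were 2.29 and 2.13. The brightest E1A probe changed by -0.16 and the others by -0.67 on average, so a single shift may be too large for bright probes.

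With the rat GAPDH probes included, 6238 probes were higher and 3588 lower at 48 h than at 0 h, 19.2% of the probes tested. The probe A_44_P1159402 rose from 4.29 ± 2.50 to 12.47 ± 0.90 (n = 3), a log2 change of 8.18 with SE 1.02 and adjusted p = 0.000221, and it was above background on 2 of the 0 h arrays. Its change was 6.79 without 0 h replicate 1 and 9.22 without 0 h replicate 2. A_64_P110798 rose by 7.79 (SE 0.72, adjusted p = 3.76e-05), or by 8.47 without 0 h replicate 2 and 7.19 without 48 h replicate 2, and was above background on 1 of the 0 h arrays. A_44_P1160463 fell by 11.27, from 14.36 ± 0.02 to 3.10 ± 1.33 (SE 0.73, adjusted p = 5.01e-06), and CUST_R2_04784 fell by 10.34, from 12.24 ± 0.27 to 1.90 ± 0.94 (SE 0.65, adjusted p = 4.07e-06). A_44_P1160463 changed by -10.56 without 48 h replicate 1 and by -11.88 without 48 h replicate 2, and at 48 h it was above background on 2 arrays. CUST_R2_04784 was above background on 1 array at 48 h. Its mean there, and the 0 h mean of A_64_P110798 (2.25), lay below the mean of the DarkCorner negative control (2.15 at 48 h and 2.57 at 0 h), so the sizes of these changes depend on values at background. At least 8-fold changes were found for 471 higher and 706 lower probes. Among the 1000 probes with the highest mean level, 329 were higher and 191 lower. The shift to equal E1A probes, chosen after seeing the data, took the median log2 change of all probes from -0.02 to 0.58. It gave 9592 higher and 1433 lower probes, so the share of rises among called probes went from 63.5% to 87.0%. A fit of only the 0 h and 48 h arrays called 2808 higher and 1746 lower.

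**Figure D2:**
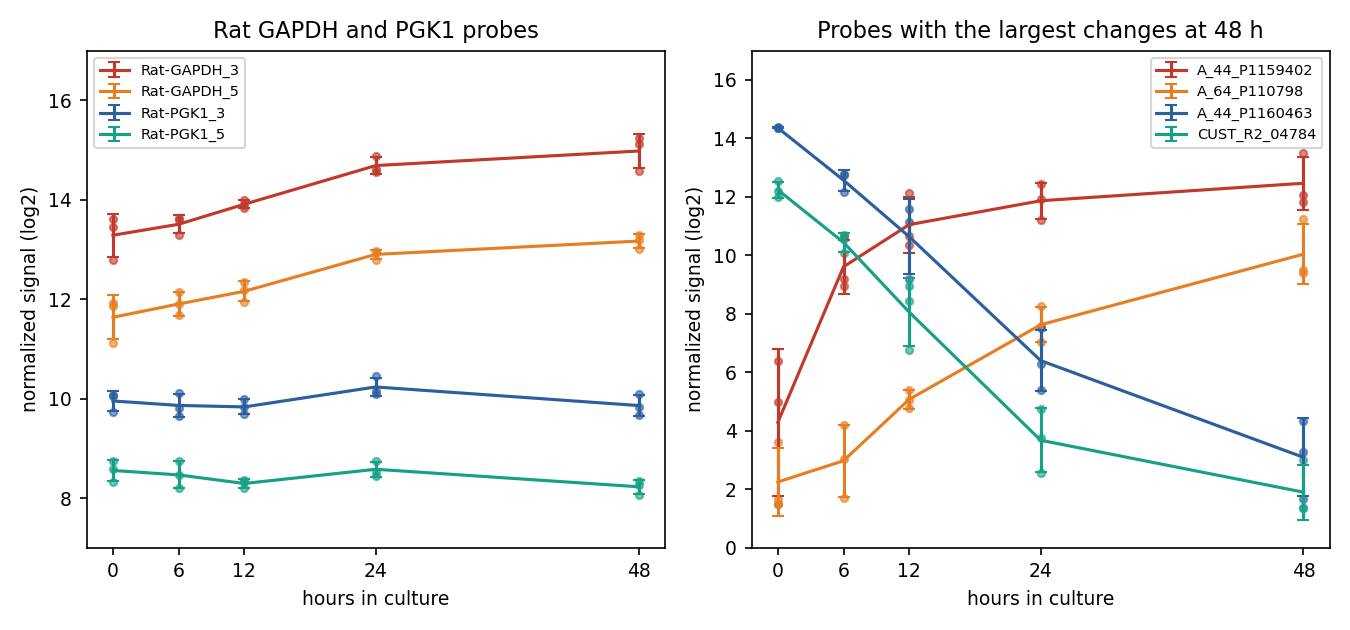
Log2 signal against hours in culture for the rat GAPDH and PGK1 probes (left) and for the probes with the largest rises and falls at 48 h (right); points are single arrays and lines join means with SD bars (n = 3). The Rat-GAPDH_3 mean goes from 13.29 to 14.98, A_44_P1160463 falls from 14.36 to 3.10, and the PGK1 differences at 48 h (-0.09 and -0.33) turn positive when arrays are shifted to equal E1A probes.

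By 6 h, A_44_P1159402 had risen by 5.32 on the log2 scale (SE 1.02, adjusted p = 0.00633), to 9.61 ± 0.92 (n = 3), or by 3.93 without 0 h replicate 1 and 6.37 without 0 h replicate 2. A_64_P110798 (0.73, adjusted p = 0.641), A_44_P1160463 (-1.79, adjusted p = 0.159) and CUST_R2_04784 (-1.80, adjusted p = 0.107) did not pass the test, although all 6 h arrays of both latter probes lay below all 0 h arrays. A_44_P1160463 passed it with the replicate block (adjusted p = 0.0285). The rat GAPDH probes differed from 0 h by 0.22 for Rat-GAPDH_3 and 0.27 for Rat-GAPDH_5 (-0.028 and 0.01 without 0 h replicate 3), and both PGK1 probes by -0.09, none of them called. Those of PGK1 were 0.15 each with arrays shifted to equal E1A probes. In all, 3700 probes were higher and 1812 lower at 6 h, 10.8% of those tested, and with the replicate block 3009 were lower. Of the 1000 probes with the highest mean level, 84 were higher and 5 lower. The E1A shift took the median log2 change of all probes from -0.06 to 0.18. It gave 2735 higher and 466 lower probes, a share of rises of 85.4% against 67.1%. Without 6 h replicate 2 the number of higher probes was 2459, and without 6 h replicate 1 the number of lower probes was 1147. A fit of only the 0 h and 6 h arrays called 1227 higher and 601 lower, lost the call of A_44_P1159402 (adjusted p = 0.101) and gained those of A_44_P1160463 (0.0292) and CUST_R2_04784 (0.0344).

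At 12 h, A_44_P1159402 (6.76, SE 1.02) and A_64_P110798 (2.83, SE 0.72) were higher than at 0 h, with adjusted p of 0.00112 and 0.0182. A_64_P110798 was above background on only 1 of the 0 h arrays, so the size of its change depends on values at background here and at 24 h. A_44_P1159402 and A_64_P110798 gave 7.81 and 3.50 without 0 h replicate 2, and A_44_P1159402 gave 5.38 without 0 h replicate 1. A_44_P1160463 fell by 3.72 (SE 0.73, adjusted p = 0.0048) and CUST_R2_04784 fell by 4.18 (SE 0.65, adjusted p = 0.00126), with -2.998 and -3.53 without 12 h replicate 1. The call of A_64_P110798 was lost without 0 h replicate 1 (adjusted p = 0.0669), 0 h replicate 3 (0.0579) or 12 h replicate 2 (0.0617). Rat-GAPDH_3 differed by 0.62 (adjusted p = 0.0971) and Rat-GAPDH_5 by 0.52 (adjusted p = 0.14); with the replicate block both passed, at adjusted p = 0.0262 and 0.0292. Without 0 h replicate 3 they differed by 0.38 (adjusted p = 0.277) and 0.27 (adjusted p = 0.394). The PGK1 differences were -0.12 and -0.26, neither called, and turned to 0.38 and 0.24 with the E1A shift. Across the array 5609 probes were higher and 2840 lower, and the replicate block raised the lower ones to 4834. The E1A shift took the median log2 change of all probes from -0.04 to 0.46. It gave 7454 higher and 913 lower, a share of rises of 89.1% against 66.4%. Without 12 h replicate 1, 3481 were higher and 1727 lower.

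At 24 h the GAPDH probes passed the test without the block. Rat-GAPDH_3 rose by 1.40 (SE 0.24, adjusted p = 0.00145) to 14.69 ± 0.17 and Rat-GAPDH_5 by 1.27 (SE 0.22, adjusted p = 0.00187) to 12.90 ± 0.09 (n = 3), with a p adjusted over the list alone of 0.00021 for each. Without 0 h replicate 3 these rises were 1.15 and 1.01. Rat-PGK1_3 (0.28, adjusted p = 0.341) and Rat-PGK1_5 (0.02, adjusted p = 0.972) did not pass; they did under the E1A shift combined with the replicate block, at 0.90 and 0.64 (adjusted p = 0.0109 and 0.0313). A_44_P1160463 fell by 7.96 (SE 0.73, adjusted p = 4.72e-05) and CUST_R2_04784 fell by 8.56 (SE 0.65, adjusted p = 1.91e-05). A_44_P1159402 rose by 7.58 (SE 1.02, adjusted p = 0.00039) and A_64_P110798 by 5.38 (SE 0.72, adjusted p = 0.000359). Without 0 h replicate 2 these rises were 8.62 and 6.05, and that of A_44_P1159402 was 6.19 without 0 h replicate 1. Across the array 6659 probes were higher and 3512 lower, 19.8% of those tested, with 5732 lower under the replicate block. The E1A shift took the median log2 change of all probes from -0.03 to 0.58. It gave 10262 higher and 1322 lower, a share of rises of 88.6% against 65.5%.

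**Figure D3:**
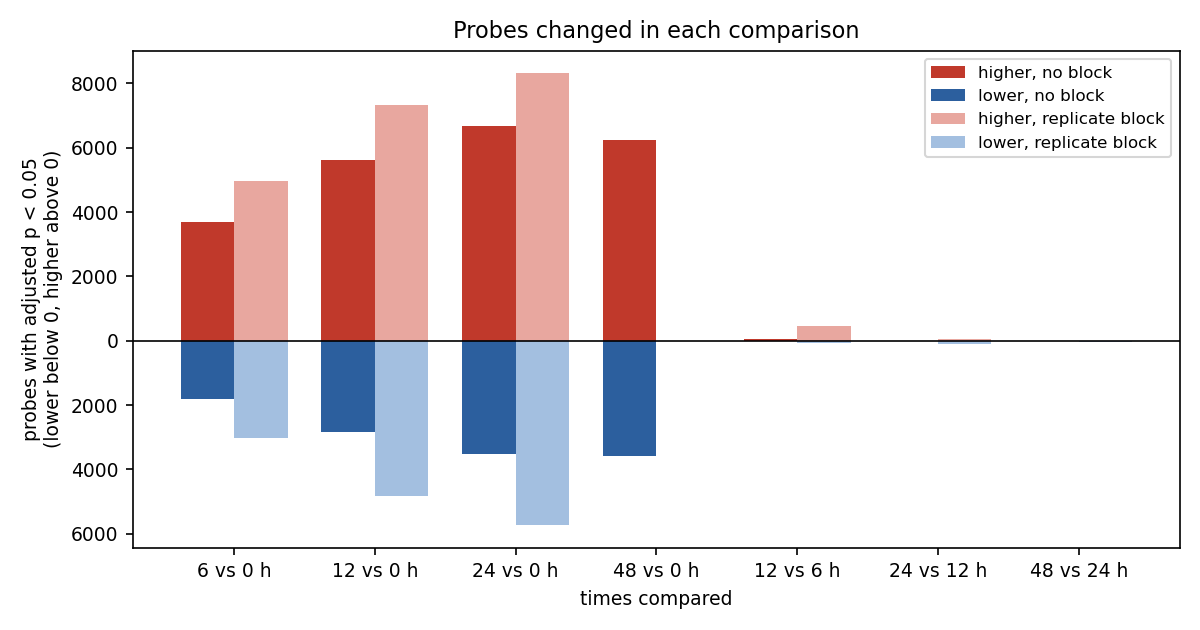
Number of probes with adjusted p under 0.05 for each pair of times, without and with the replicate number as a block. The vertical axis shows higher probes above 0 and lower ones below 0. The block is not drawn for 48 h against 0 h, where numbers 1 and 2 missed the correlation limit of 0.1. Against 0 h the higher probes number 3700, 5609, 6659 and 6238 at 6, 12, 24 and 48 h without the block, while steps between neighbouring times call at most 65 in a direction without the block and 469 with it.

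Between neighbouring times few probes passed. Neither the GAPDH probes nor the PGK1 probes did: from 12 to 24 h Rat-GAPDH_3 differed by 0.78 (adjusted p = 0.351) and Rat-GAPDH_5 by 0.74 (adjusted p = 0.343), although adjusted over the list alone both had adjusted p = 0.0129 by limma. From 6 to 12 h, 65 probes were higher and 9 lower, and with the replicate block 469 and 61. From 12 to 24 h, 1 was higher and 3 lower (60 and 112 with the block), and from 24 to 48 h, 2 were higher and 15 lower (6 and 38). At an unadjusted p under 0.05, 5311, 3359 and 2165 probes passed in these steps. Chance alone passes a share of 0.05 of the 51259 probes if none changed and arrays are independent. The first and second counts lay above that share and the third, from 24 to 48 h, lay below it. These counts are therefore not read as numbers of changed probes. Probes whose arrays did not overlap made up 16.03%, 12.9% and 8.10%, where chance gives 10% for independent arrays and less where arrays of one number deviate together, so the shares are not set against it here. From 6 to 12 h the E1A shift gave 6 higher and 0 lower probes, and together with the replicate block 1323 and 51. Without the block that shift also changes the spread of single probes, so its counts mix scale and precision. Fits of only the 2 times compared called 0 probes in either direction in every step. Without 12 h replicate 1, the 65 became 12, without 6 h replicate 3 or 12 h replicate 3 it became 13, without 12 h replicate 2 it became 20, without 24 h replicate 3 or 48 h replicate 3 it became 27, without 24 h replicate 2 it became 30 and without 6 h replicate 1 it became 39. In the later steps, leaving out 1 array gave at most 44 probes from 12 to 24 h and 74 from 24 to 48 h in either direction.

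Any difference among the 5 times was found for 10673 probes by the F test. Among these probes the mean was lowest at 0 h for 5383 (50.4%) and highest at 0 h for 2908 (27.2%). Means rose at every step for 1207 (11.3%), as A_44_P1159402 and A_64_P110798 did, and fell at every step for 1033 (9.68%), as A_44_P1160463 and CUST_R2_04784 did. A random order of the 5 means gives 0.833% for each. That is no fair baseline here, since the probes were picked by a test of differences from 0 h.

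Of the 3700 probes higher at 6 h, 2437 (65.9%) were also higher at 48 h, among them A_44_P1159402. Of the 1812 lower at 6 h, 928 (51.2%) were also lower at 48 h. Independent lists would share 450.3 and 126.8. In 50 simulated sets of unchanged groups limma called no probe, and lists of the same lengths taken by p from those sets shared a median of 1596.5 (1528 to 1681) and 691 (638 to 749). With the E1A shift 245 probes were lower at both times. With only 3 arrays at 0 h the controls could not be split, so part of these overlaps may come from the shared controls. Of the probes higher at 6 h, 540 (14.6%) were lower at 48 h than at 6 h, and of those lower at 6 h, 489 (27.0%) were higher. At 48 h against 0 h, 416 of the 540 and 430 of the 489 were not called. Further change in the same direction from 6 to 48 h was called for 140 and 111 probes. The comparisons of 6 h with 0 h and 48 h with 6 h share the 6 h arrays with opposite sign, which favours opposite calls. The simulated lists of unchanged groups gave 737 (688 to 777) and 660 (606 to 694), above 540 and 489. Those lists hold noise alone, forced to the observed lengths, so they cannot decide whether probes returned towards the 0 h level. With the replicate block the opposite calls numbered 925 and 900. Sets simulated and fitted with the block gave 1193.5 (1135 to 1251) and 1167 (1120 to 1220), again above both. The E1A shift gave 138 and 114. The 540 became 343 without 6 h replicate 1, 330 without 6 h replicate 2 and 355 without 48 h replicate 3; without 6 h replicate 1 the 489 became 317 and the 928 became 611.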

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

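The tests of the E1A probes and of the replicate numbers, the E1A shift and the count of rises by their 0 h signal were chosen after the result was seen; the test by mean level and the counts of other splits were written before.

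The mouse and human GAPDH probes, controls left out of every comparison, drew attention because some gave higher signal at 48 h, as the rat ones did. Since the arrays were given RNA of rat cells, these probes may report the same rat transcripts and are no independent evidence. From 0 to 48 h the log2 difference was 1.75 for Human-GAPDH_3, 1.40 for Human-GAPDH_5 and 1.62 for Mouse-GAPDH_5, with every 48 h array above every 0 h array. Mouse-GAPDH_3 differed by 1.11 with overlapping arrays. Of the PGK1 controls, Human-PGK1_3 averaged 6.87 at 0 h and 5.36 at 48 h, Human-PGK1_5 averaged 6.85 and 6.35, and Mouse-PGK1_5 averaged 8.47 and 8.05, with every 48 h array below every 0 h array, while Mouse-PGK1_3 differed by -0.17 with overlapping arrays. Under the E1A shift Human-PGK1_3 stayed lower, at -0.90, while Human-PGK1_5, Mouse-PGK1_5 and Mouse-PGK1_3 turned to 0.10, 0.17 and 0.43. Exact permutation of 3 arrays against 3 cannot give a p below 0.1.

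E1A control probes, which do not measure rat RNA, averaged 8.09 at 0 h and 7.49 at 48 h (7 probes, n = 3, exact p = 0.1, the smallest possible). A single shift of the deposited values of the whole array is argued against as the whole cause. The brightest E1A probe changed by -0.16 and the others by -0.67 on average, a gap of 3.11 SE (3.115, unpaired, 3 arrays against 3). Setting arrays to a common distribution can make an earlier single shift unequal across levels, so a shift before that step is not decided here. A time effect on dim signals of all kinds cannot be told apart from other causes: tested probes of similar level had a median change of 0.09 (0.0868), but the common distribution of the arrays holds that median near 0. Other values go with it: the DarkCorner negative control went from 2.57 to 2.15 with every 48 h array below every 0 h array. Of the 46 controls other than E1A, GAPDH and PGK1, 41 had a lower mean at 48 h. Some of the 41 have IDs starting with DCP and may report the same RNA as the E1A probes. At 0 h DCP_1_0 averaged 12.68 and (+)E1A_r60_1 12.71, while DCP_20_0 averaged 5.405 and (+)E1A_r60_a20 5.345. The 41 are therefore not all separate evidence from the E1A probes. More rat signal per array at later times could also lower the E1A probes and the other controls relative to it, and this biological explanation was not tested.

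Arrays with the same replicate number deviated together at most times. The E1A probes also deviated by number, with exact permutation p = 0.000772, and the number carried 87.3% of their spread within times. Arrays of one number processed together and a shared animal per number cannot be told apart by this: the controls carry no animal's RNA, but in arrays set to a common distribution a difference in rat signal could move them too.

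More probes rose than fell at 48 h. Dim probes lifted from background are argued against as the whole cause, because 4601 of the 6238 higher probes were above the negative controls on every 0 h array, and these alone outnumber all 3588 lower probes. Rises made up 65.1% of called probes above the median level, but a lifted probe can enter that set through its own rise, as 1063 with a 0 h mean below the median of all values did, so this share decides nothing. Too high a scale of the 48 h arrays stays open: equalising the E1A probes moved the share to 87.0% (87), but those probes were already known to be lower at 48 h, so that shift was bound to raise the share and decides nothing. Too high a scale would raise control probes, whereas 41 of the 46 controls other than E1A, GAPDH and PGK1 had a lower mean at 48 h. Their direction is opposite, but other causes of their fall were not separated, so this does not exclude it. Other effects of the authors' normalization and a biological difference with time in culture stay open and could not be separated here.

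For each comparison of a pair of times the 6 arrays allow 10 splits, too few for a share under 0.05, and 1 of the 10 (the real one) reached the real count each time. The real counts against 0 h were 5512, 8449, 10171 and 9826 at 6, 12, 24 and 48 h, and the highest other splits gave 137, 2, 1 and 3. For the steps the real counts were 74, 4 and 17 and the highest others 0, 3 and 3. Of the 4 splits that part every replicate number, the real one included, the others gave at most 1. For the F test, 1 of 100 regroupings reached 10673 probes, the real one, and the highest other gave 3977. Chance regrouping is thus excluded for it only where arrays are regrouped without regard to replicate number. Regroupings that part every number were not counted for this test.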

How the results depend on the processing

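The E1A shift, its combination with the replicate block and the floor at the lowest value of 6 h replicate 3 were chosen after seeing the data. Counts are given as higher and lower; where not said, the cause of a move was not tested. Shifts to equal medians or 75th percentiles and renewed quantile normalization moved no result beyond its limit, but the arrays already share 1 distribution, so this says nothing about stability. Probe summaries per gene, gene lists and camera were not run, since probes had no gene names. Dim signal limits the calls: of the probes called at 48 h, 597 were at or below the negative control on all 0 h arrays and 308 on all 48 h arrays.

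With the replicate block, lower probes numbered 3009, 4834, 5732 and 5606 at 6, 12, 24 and 48 h against 0 h, the steps gave 469 and 61, 60 and 112, and 6 and 38, probes lower at both 6 and 48 h numbered 1595, and those called in opposite directions at 6 h against 0 h and 48 h against 6 h (opposite calls, by their direction at 6 h) 925 and 900. At 48 h against 0 h the arrays did not meet the pairing limit, and the block gave 7934 higher probes there. Among single probes the block added calls for both rat GAPDH probes at 12 h and for A_44_P1160463 at 6 h, and it changed no other call.

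With the E1A shift, lower probes numbered 466, 913, 1322 and 1433 against 0 h and higher ones 10262 and 9592 at 24 and 48 h. The number carried 87.3% of the E1A spread within times, so the shift changed the spread of other probes as well as their scale. For Rat-GAPDH_3 the SE went from 0.24 to 0.40, and was 0.23 with the block as well. It also rose for the other rat GAPDH and PGK1 probes but fell for the probes picked by size, as from 0.73 to 0.54 for A_44_P1160463. Counts under the shift without the block mix both effects. The step from 6 to 12 h gave 6 and 0, that from 12 to 24 h 11 lower and that from 24 to 48 h 1 higher; 245 probes were lower at both 6 and 48 h, and 138 and 114 had opposite calls. The shift reversed the uncalled PGK1 differences at 6, 12 and 48 h to 0.15, 0.38 and 0.51 for Rat-PGK1_3 and to 0.15, 0.24 and 0.27 for Rat-PGK1_5, with or without the block. With the replicate block as well, counts against 0 h were 6258 and 1494 at 6 h, 14230 and 1828, 19085 and 2150, and 18981 and 2293, the steps gave 1323 and 51, 31 and 78, and 10 and 49, the F test 18671, and 5431 probes were higher at both 6 and 48 h.

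Tests against a 1.5-fold change (treat), which give no F test, ask for more. They called 1 higher from 12 to 24 h, as without treat, and fewer in the other counts: 1119 and 291, 1811 and 771, 2552 and 1388, and 2475 and 1513 against 0 h, 8 and 0 from 6 to 12 h, 0 lower from 12 to 24 h, 0 and 8 from 24 to 48 h, 615 and 159 at both 6 and 48 h, and 74 and 36 opposite calls. A minimum 2-fold change left 304 opposite calls among probes lower at 6 h. Fits of only the 2 times compared called 1227 and 601 at 6 h and 2808 and 1746 at 48 h. They called 0 in either direction in every step, 596 and 234 at both times, and 88 and 71 opposite calls. Against 0 h at 12 and 24 h they moved no count beyond its limit. Fewer arrays alone therefore do not explain the moves at 6 and 48 h. The main fit pools a single spread per probe over all times. Same-time arrays correlated at 0.923 to 0.934 at 0 h, 0.936 to 0.954 at 6 h and 0.945 to 0.958 at 48 h. At 12 and 24 h they correlated at 0.962 to 0.970. The pooled SE may thus be too small for 6 and 48 h against 0 h, which was not tested. With trend and robust settings the steps gave 32 and 3, 5 and 19, and 4 higher from 24 to 48 h. Leaving out the dimmest probes gave 6 and 20 from 12 to 24 h and 1 higher from 24 to 48 h, and the floor gave 5 and 7, and 1.

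With 1 array left out, counts ranged over 2459 to 3884 and 1147 to 1951 at 6 h, 3481 to 5825 and 1727 to 3091 at 12 h, 12 to 96 and 0 to 17 from 6 to 12 h, 1 to 14 and 0 to 44 from 12 to 24 h, and 0 to 24 and 6 to 74 from 24 to 48 h. Probes lower at both 6 and 48 h ranged from 611 to 1034, and opposite calls from 330 to 622 and from 317 to 468. The lowest came without 6 h replicate 2 or 1 at 6 h, without 12 h replicate 1 at 12 h, and without 12 h replicate 1 or 3 from 6 to 12 h; 48 h replicate 3 gave the 24, the 74 and the 44, and 48 h replicate 1 the 14. Uncalled differences changed sign within -0.028 to 0.38 for Rat-GAPDH_3 at 6 h, -0.22 to 0.016 and -0.23 to 0.044 for Rat-PGK1_3 and Rat-PGK1_5 at 6 h, -0.088 to 0.12 for Rat-PGK1_5 at 24 h and -0.21 to 0.0056 for Rat-PGK1_3 at 48 h.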

Other observations

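The test of the probe kinds was written after the unweighted shares, though before the weighted share, had been seen; the comparison of probe ends was chosen after seeing the data.

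A smaller share of the probes with IDs starting with CUST was called than of those starting with A, a difference given without a test of its own. At 48 h against 0 h, 2126 CUST probes were higher and 1058 lower (15.3% of 20837), against 4110 and 2530 A probes (21.8% of 30418). Lower signal of the CUST probes is argued against as the whole reason, since their share weighted to the levels of the A probes was 17.7% (17.75). What the CUST probes measure is not given in the sources used here, and no other explanation was tested.

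The log2 difference between the 2 rat GAPDH probes, Rat-GAPDH_3 minus Rat-GAPDH_5, was 1.65 ± 0.11 at 0 h and 1.81 ± 0.23 at 48 h (n = 3, exact permutation p = 0.4). For Rat-PGK1_3 minus Rat-PGK1_5 it was 1.40 ± 0.10 and 1.63 ± 0.20 (n = 3, exact permutation p = 0.2). The smallest p this design allows is 0.1.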
